A study of Homo sapiens with 4 samples.

How the data were processed

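Gene expression was measured with 4 Affymetrix human arrays of 54675 probe sets, 1 array for each combination of siRNA and treatment. Ea.hy926 cells, a hybrid line made by fusing human umbilical vein endothelial cells with the lung carcinoma line A549, received 50 nM control siRNA or siRNA against TCF11, per the labels. TCF11 is the long form of NFE2L1, a transcription factor of the cap'n'collar family. The siRNA time in the labels is 48 h. Cells were treated for 24 h with 10 nM epoxomicin, an irreversible inhibitor of the proteasome, or with 0.1% DMSO, its solvent.

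The values used were the deposited linear signal intensities, 1 per probe set and array. The submitters' processing notes name MAS5 and GCRMA, without versions and without saying which gave the deposited values. From the values, the mean signal intensity of each deposited array after trimming 2% of probe sets at each end was 500.1, so the arrays had been scaled to a common trimmed mean. Their distributions were not identical, so they had not been quantile normalized. Calls of presence or absence were not used here. Scaling to a common mean makes each difference relative to the bulk of the array. It removes any general change in the amount of mRNA per cell.

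Of the probe sets, 41097 were paired with exactly 1 gene in the platform annotation, 1801 with several genes, and 11777 had no gene listed there. The Entrez identifiers of 41043 of the single-gene probe sets matched the reference gene table, from which current symbols were taken. The 62 control probe sets were kept apart. Genes were named only from single-gene probe sets, which left 19775 genes, of which 10523 had 2 or more probe sets. HSPA1A and HSPA1B, which were chosen for naming beforehand, had no single-gene probe set and have no values here.

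Signals were taken to log2 after values under a floor had been raised to it. The floor was the median of all single-gene probe set values on the 4 arrays, a signal of 104. A gene's value was that of its single-gene probe set with the highest mean log2 signal. A gene entered a comparison when at least 1 of the arrays compared was above the floor. A difference with 1 side at or under the floor is a lower bound on the fold and is written as at least that fold.

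The 5 comparisons were epoxomicin against DMSO with each siRNA, TCF11 siRNA against control siRNA in each treatment, and the difference of the 2 epoxomicin effects. With 1 array per group there was no replicate error, so no p-value, standard error or test was computed, and the number of arrays limits the precision. Genes with a log2 difference of at least 1 in size, which is 2-fold, were counted as a description. As a technical gauge, the SD of log2 differences between probe sets of the same gene was pooled over genes, which covers neither cultures nor RNA preparations.

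Lists of genes (26 in number) were fixed before the data were examined, as were the comparisons, the floor, the naming rule and the alternatives. The median log2 difference of each list was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression so as to match its members (seed 1). The percentile, and whether the median lay outside the central 95% of random lists, describe these arrays and do not test the conditions. Named genes were the 10 with the largest positive and the 10 with the largest negative difference among genes above the floor on all arrays compared, the 3 largest bounds each way, the extreme members of each list, and a fixed set around NFE2L1, the proteasome and stress responses. Other list members were picked as examples after their values were seen. Where probe sets of a named gene differed in sign, this is said or their range is given for the genes leading a comparison.

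The calculation was tested on simulated arrays for the epoxomicin comparison with control siRNA, over 11258 genes with noise of SD 0.2 in log2. At a true log2 difference of 1.5, 97.0% of genes passed the 2-fold threshold, as did 1.49% at 0.5 and 0.045% of unchanged genes. Changes, and the list shift below, were planted only in genes far above the floor. The noise was set per array, equal at every signal level and independent between genes. The 97.0%, 1.49% and 0.045% therefore do not hold for dim genes, and no rate covers genes that vary together or differences between cultures. The 0.045% is not a rate of false calls on the real arrays. A list of 30 genes shifted by 0.5 had a recovered median of 0.57, above all random lists, and 3.50% of 200 unshifted lists lay outside the central 95%.

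Alternatives were no floor, a floor at the 25th or 75th percentile, centring on the median, quantile normalization, the median of a gene's probe sets, leaving out probe sets with suffixes marking possible cross-hybridization (_s_at and _x_at), thresholds of 1.5-fold or a log2 difference of 1.5, list means, and random lists not matched on expression. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genome coordinates were not used here.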

Results

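Ea.hy926 cells carrying control siRNA or TCF11 siRNA were profiled after DMSO or epoxomicin, with 1 array per group and no replicates, so that no difference here has a replicate check. The median signal over probe sets was 75.5 with control siRNA and DMSO, 78.1 with control siRNA and epoxomicin, 82.7 with TCF11 siRNA and DMSO, and 77.7 with TCF11 siRNA and epoxomicin. Between 10934 and 11335 genes were above the floor on an array. Log2 signals of pairs of arrays correlated across probe sets at 0.905 to 0.921. The log2 difference between the 3' and 5' probe sets of ACTB, a sign of RNA integrity, was 0.59 and 0.80 on the DMSO arrays and 1.10 and 0.97 on the epoxomicin arrays, in the order control and TCF11 siRNA. For GAPDH it lay between -0.13 and -0.04 on all 4 arrays. Log2 differences between probe sets of the same gene had a pooled SD of 0.30 to 0.36 in the 4 direct comparisons and 0.43 in the difference of the epoxomicin effects.

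The target of the siRNA was examined first. NFE2L1, the gene that encodes TCF11, had lower signals with TCF11 siRNA in all 3 of its probe sets. In DMSO the brightest probe set had a signal of 3263 with control siRNA and 816 with TCF11 siRNA, so that 25% was left, and the other 2 probe sets kept 27.6% and 35.9%. In epoxomicin the brightest probe set had a signal of 5090 with control siRNA and 1322 with TCF11 siRNA, so that 26% was left, and the other 2 kept 26.1% and 22.6%. NFE2L1 had the most negative measured difference of all genes above the floor on both DMSO arrays. Whether these probe sets separate TCF11 from the other products of NFE2L1 was not determined here. All 3 carry the suffix _s_at or _x_at, which marks possible cross-hybridization. NFE2L2, the gene of the related factor NRF2, had log2 differences between TCF11 siRNA and control siRNA of 0.14 in DMSO and 0.14 in epoxomicin. NFE2L3, the third gene of this branch of the family, had differences of 0.07 in DMSO and -1.18 in epoxomicin, and the probe sets of both genes differed in sign in DMSO. NFE2L1 itself had a log2 difference between epoxomicin and DMSO of 0.64 with control siRNA and 0.70 with TCF11 siRNA, where its probe sets ranged from -0.01 to 0.70.

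The first comparison asked how expression differed under proteasome inhibition in cells with control siRNA. All 28 measured genes of the 20S and 19S proteasome subunits were higher with epoxomicin, with a median log2 difference of 0.66, which is 1.57-fold. CXCL8, the gene of the chemokine interleukin 8, was 17.9-fold higher, HSPB8, a small heat shock protein, 9.94-fold, GABARAPL1, an autophagosome protein, 9.24-fold, and DDIT3, the stress transcription factor CHOP, 7.28-fold. All 24 measured mitotic genes were at least 2-fold lower, with a median log2 difference of -1.80. Of 11636 genes compared, 419 were at least 2-fold higher and 456 at least 2-fold lower.

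Among proteasome genes with control siRNA, the 13 measured genes of the 20S core, the proteolytic barrel, had a median log2 difference of 0.54, at percentile 100 of the random lists. PSMB5, a catalytic subunit that epoxomicin binds, went from a signal of 9200 in DMSO to 17867 in epoxomicin, a log2 difference of 0.96. PSMA7 had the smallest difference, 0.16. The 15 measured genes of the 19S regulator, which recognizes and unfolds substrates, had a median of 0.70, also at percentile 100. PSMC4, an ATPase subunit, had a log2 difference of 1.18 and was the only one of the 28 subunit genes at least 2-fold higher. The 4 measured genes of the immunoproteasome and its PA28 activator were all lower, with a median of -0.91 at percentile 0.26, among them PSMB8 at -1.18 and PSMB10 at -1.02. Genes of proteasome assembly and other activators had a median of -0.06, inside the random range, although ECPAS and the assembly factor POMP had differences of 0.76 and 0.60.

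Of 3 lists of genes that act upstream of the proteasome, 2 lay above the random range with control siRNA. The list of p97/VCP, the ATPase that extracts ubiquitinated proteins, and its cofactors had 16 of 19 members higher and a median of 0.56 at percentile 100. Its member ZFAND2A, an arsenite-inducible protein, had a log2 difference of 2.47, and VCP itself 0.99. The list of degradation from the endoplasmic reticulum had 13 of 16 members higher and a median of 0.29 at percentile 98.4, with DERL2 at 0.78 and HERPUD1 at 0.73. The list of ubiquitin genes and enzymes had a median of 0.11, inside the random range. Its lowest member was UBE2C, a conjugating enzyme of mitosis, at -1.71.

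Chaperone and stress lists lay above the random range with control siRNA. Chaperones of the endoplasmic reticulum had 17 of 18 members higher and a median of 0.51 at percentile 100, with DNAJB9 at 1.46, DNAJC3 at 1.18 and HSP90B1 at 1.06. The cytosolic heat shock list had 15 of 21 members higher and a median of 0.28 at percentile 99.7. DNAJB2 and DNAJB4, at 1.67 and 1.14, were its other members at least 2-fold higher besides HSPB8. The integrated stress response list, named for the factor ATF4, had 20 of 26 members higher and a median of 0.29 at percentile 99.7, with ATF3 at 1.81 and TRIB3 at 1.45. Autophagy genes had 12 of 19 members higher and a median of 0.33 at percentile 99.7, with OPTN at 1.36 and MAP1LC3B at 1.19. The autophagy receptor SQSTM1 had a difference of 1.13, but its probe sets ranged from -0.37 to 2.61, and without the _s_at and _x_at probe sets its value was -0.37.

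Antioxidant and inflammatory genes were higher as well. The list of NRF2 antioxidant genes had 22 of 25 members higher, 11 of them at least 2-fold, and a median of 0.44 at percentile 100. Among them were OSGIN1 at 2.67 or more, the aldo-keto reductase AKR1B10 at 2.63, the heme oxygenase HMOX1 at 2.52 and GCLM, a subunit of the enzyme that starts glutathione synthesis, at 1.77. NQO1, a quinone reductase often used as a marker of NRF2, had a difference of -0.03. The list of NF-kappaB and inflammatory genes had 13 of 16 members higher and a median of 0.65 at percentile 100, with CXCL2 at 1.88, CXCL3 at 1.55 and IL6 at 1.37. The list of interferon-stimulated genes had 14 of 19 members higher and a median of 0.38 at percentile 99.7, led by IFI44 at 1.70. Transcription factors and regulators around NFE2L1 had a median of 0.40 at percentile 99.4, with MAFG and MAFF, small MAF partners of these factors, at 1.10 and 1.05.

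Cell division genes were lower with control siRNA. Mitotic genes lay at percentile 0, with TOP2A, the topoisomerase of dividing cells, at -2.53, ASPM at -2.24, DLGAP5 at -2.18 and the proliferation marker MKI67 at -2.10. The brightest TOP2A probe set gave this value, and its 3 probe sets ranged from -2.53 to -0.21. All 26 measured DNA replication genes were lower, 13 of them at least 2-fold, with a median of -1.03 at percentile 0. CDT1, a licensing factor, had a difference of -1.81 and RRM2, a ribonucleotide reductase subunit, -1.72, and CCNE1, the gene of cyclin E1, had the smallest at -0.41. The ACTB 3' to 5' difference was also 1.10 on this epoxomicin array against 0.59 on the DMSO array.

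Outside the lists, the largest positive differences with control siRNA among genes above the floor on both arrays were those of CCN3, a matricellular protein, 6.88-fold higher, GLRX, a glutaredoxin, 6.88-fold, NXPE3 6.09-fold and MMP10, a matrix metalloproteinase, 5.97-fold. The cytokine gene IL1A was at least 6.64-fold higher, GCNT3 at least 6.79-fold and NAP1L2 at least 9.79-fold. Among the same genes the most negative differences were those of DHRS2, a short-chain dehydrogenase, 9.63-fold lower, APLN, the gene of the peptide apelin, 7.87-fold, and PLXNA4, a plexin receptor, 6.91-fold. NTM, EDN1, the gene of endothelin 1, KRT80, KIF15 and HMGB3 were between 4.56-fold and 5.40-fold lower. KSR2 was at least 5.87-fold lower, KIFC1 at least 5.84-fold and XXYLT1 at least 4.22-fold.

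**Figure D1:**
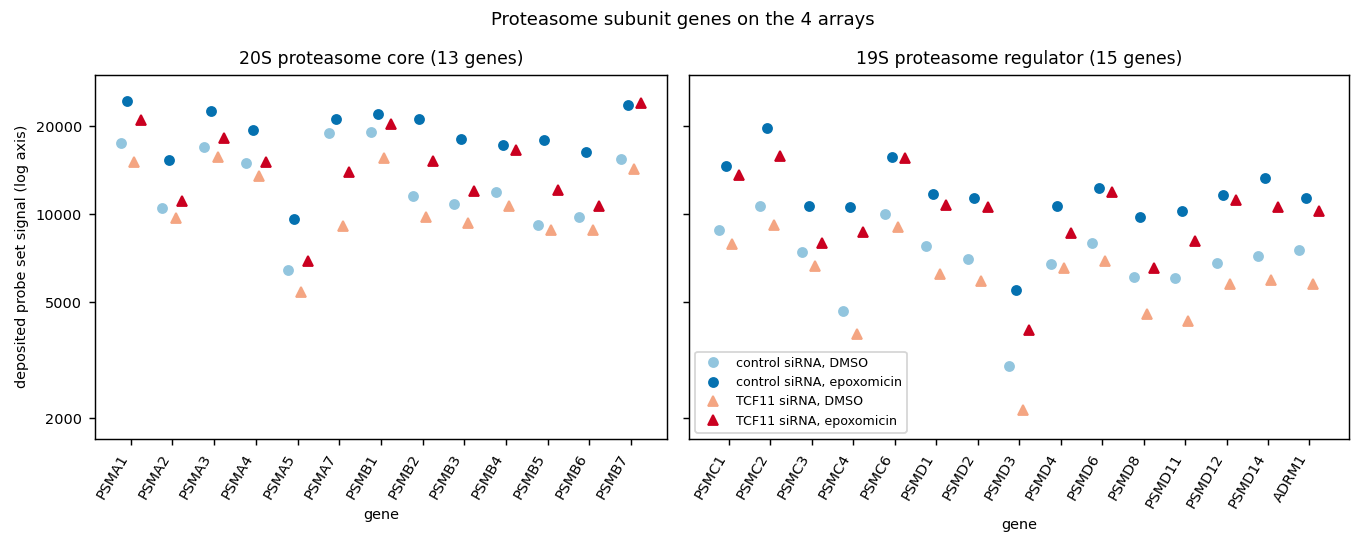
Deposited signal (log axis) of 13 genes of the 20S core and 15 genes of the 19S regulator on the 4 arrays, 1 point per array, circles for control siRNA and triangles for TCF11 siRNA. Each gene lies higher with epoxomicin than with DMSO under the same siRNA, with medians of 0.66 and 0.63 in log2, and 27 of 28 lie lower with TCF11 siRNA than with control siRNA in epoxomicin.

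The same treatment was then compared in cells with TCF11 siRNA. All 28 proteasome subunit genes were again higher with epoxomicin, with a median log2 difference of 0.63, which is 1.55-fold. The largest positive differences among genes above the floor on both arrays were those of MMP10, 17.3-fold higher, CXCL8, 14.0-fold, and INHBA, the gene of an activin subunit, 12.4-fold, followed by DDIT3 with a log2 difference of 3.39 and HSPB8, 8.92-fold. Cytosolic heat shock genes were a median of 2.01-fold higher, and DNA replication genes had a median log2 difference of -2.17, with 24 of 26 at least 2-fold lower. Of 11774 genes compared, 487 were at least 2-fold higher and 1005 at least 2-fold lower.

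With TCF11 siRNA the 20S core genes had a median difference of 0.38 at percentile 99.2, from PSMA4 at 0.16 to PSMB7 at 0.76. PSMB5 went from 8834 in DMSO to 12053 in epoxomicin, a log2 difference of 0.45. The 19S regulator genes had a median of 0.79 at percentile 100, led by PSMC4 at 1.16, with PSMD12 at 0.96 and PSMD1 at 0.78. The immunoproteasome and PA28 genes had a median of -1.21 at percentile 0.24, with PSMB9 at -1.82 and PSMB10 at -1.62. Assembly and activator genes had a median of -0.43 at percentile 0.55, with the chaperone gene PSMG4 at -1.55. The p97/VCP list had a median of 0.75 at percentile 100, with ZFAND2A at 2.92 and VCP at 1.13. Degradation from the endoplasmic reticulum had a median of 0.47 at percentile 99.8, with HERPUD1 at 1.81 and SEL1L at 1.09. The ubiquitin list had a median of 0.31, inside the matched range but above that of random lists not matched on expression, at percentile 97.9, and above the range after quantile normalization, at percentile 98.4.

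Heat shock genes were higher in 21 of 22 members with TCF11 siRNA, 11 of them at least 2-fold, at percentile 100. HSPB8 had a difference of 3.16, the cochaperone DNAJB1 2.11, the small heat shock protein HSPB1 1.79 and the cochaperone BAG3 1.60. Chaperones of the endoplasmic reticulum had a median of 0.94 at percentile 100, 8 of 18 being at least 2-fold higher, with DNAJB9 at 1.85, HSP90B1 at 1.77, HYOU1 at 1.63 and HSPA5, the chaperone BiP, at 1.41. The integrated stress response list had a median of 0.59 at percentile 100, with ATF3 at 3.15 and SLC3A2, an amino acid transporter chain, at 1.76. Its members PSPH and PSAT1, enzymes of serine synthesis, had differences of -1.30 and -1.11. Autophagy genes had a median of 0.45 at percentile 99.9, with GABARAPL1 at 2.72 and MAP1LC3B at 1.79.

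The NRF2 list had 20 of 25 members higher with TCF11 siRNA and a median of 0.37 at percentile 99.8, and 4 members were at least 2-fold higher. These 4 were OSGIN1 at 2.22, the cystine transporter SLC7A11 at 2.13, HMOX1 at 1.69 and GCLM at 1.32, whereas the epoxide hydrolase EPHX1 had a difference of -1.55. NF-kappaB and inflammatory genes had a median of 0.32 at percentile 98.96, with IL6 at 1.35 and CCL2, a monocyte chemokine, at -1.24 or lower. Interferon-stimulated genes had a median of -0.10, inside the random range, with IFIT1 at 2.19 and OAS3 at -1.59. MAFF and the repressor BACH1 had differences of 1.49 and 1.20, and NFE2L3 had -1.20. The regulator list as a whole had a median of 0.34 at percentile 96.8, inside the matched range, and lay above it after quantile normalization, at 0.38, and without matching.

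All 24 mitotic genes were at least 2-fold lower with TCF11 siRNA as well, with a median of -2.52 at percentile 0. DLGAP5 was 9.19-fold lower, the kinase gene CDK1 8.52-fold and TOP2A 8.02-fold. Replication genes lay at percentile 0, with RRM2 and MCM2, a subunit of the replicative helicase, both at -2.73, and CCNE1 at -0.04. The ACTB 3' to 5' difference was 0.97 on this epoxomicin array against 0.80 on the DMSO array.

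Among single genes with TCF11 siRNA, the growth factor gene HBEGF was 7.25-fold higher, KBTBD8 6.79-fold, and NEDD9, ERO1B and RELN at least 4.81-fold, 4.21-fold and 3.77-fold. The probe sets of NEDD9 differed in sign. KCTD12 was 11.5-fold lower, OIP5 10.4-fold, PBK, a mitotic kinase, 9.68-fold and KIF15, a mitotic kinesin, 9.55-fold. SPC25, a kinetochore protein, was 8.27-fold lower, and of the cystatin genes CST4 was 7.87-fold lower and CST1 had a log2 difference of -3.17. ZNF367 was at least 7.99-fold lower, GINS4 at least 7.41-fold and the fatty acid elongase ELOVL6 at least 7.30-fold.

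Across 11147 genes the 2 epoxomicin effects, which share no array, had a Pearson correlation of 0.65 and a Spearman correlation of 0.59. Genes are not independent replicates. At least 2-fold higher with both siRNAs were 169 genes, where independent lists would share 17.7, and 322 were at least 2-fold lower with both, where independent lists would share 40.8. With no floor the Pearson correlation was 0.15.

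**Figure D2:**
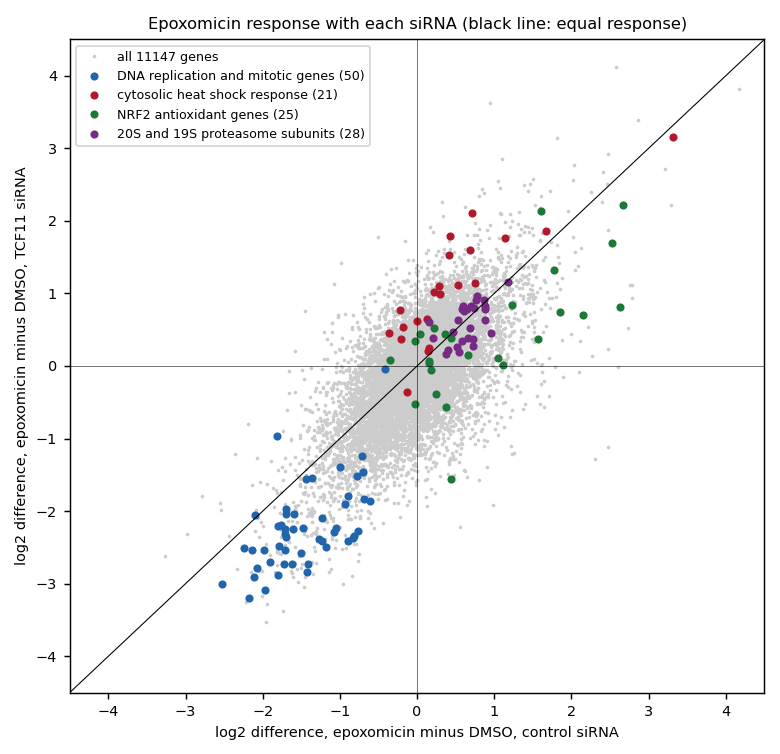
Log2 difference between epoxomicin and DMSO with control siRNA (x axis) and with TCF11 siRNA (y axis), 1 point per gene for 11147 genes, with 4 groups of genes coloured. The black line marks equal responses, and replication and mitotic genes lie mostly under it, with medians of -1.55 on the x axis and -2.30 on the y axis.

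The effect of TCF11 siRNA without proteasome inhibition was smaller in number of genes. NFE2L1 itself was 4-fold lower, and the 28 proteasome subunit genes were all lower, with a median log2 difference of -0.22 and a range of -1.05 to -0.04. After quantile normalization 26 of the 28 were lower, with a median of -0.17. Metallothionein genes, which encode metal-binding proteins, were lower in all 6 measured members, with a median of -0.70. Of 11743 genes compared, 101 were at least 2-fold higher and 45 at least 2-fold lower, so that 69.2% of them were higher. That share was 57.7% after centring on the median, with 82 higher and 60 lower, and 54.5% after quantile normalization, with 72 higher and 60 lower. It turned to 44.8% with the floor at the 75th percentile, with 13 higher and 16 lower. The added poly-A control transcripts had a median log2 difference of -2.00 in this comparison.

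In DMSO the 19S genes had a median of -0.25 at percentile 0.07, with PSMD3 at -0.51 and PSMD11 at -0.49. The 20S genes had a median of -0.16 at percentile 5.61, inside the random range, and -0.13 at percentile 0.935 after quantile normalization. PSMA7 had a difference of -1.05 and was the only subunit gene at least 2-fold lower, whereas PSMB5 had -0.06. Metallothioneins lay at percentile 0, from MT1E at -1.26 to MT1G at -0.44. These genes are near copies of each other, and cross-hybridization among them was not excluded. GCLM, at -1.01, was the only NRF2 list member at least 2-fold lower, and that list as a whole had a median of -0.05, inside the random range.

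Mitotic and replication genes were slightly lower with TCF11 siRNA in DMSO, with medians of -0.31 and -0.35, both at percentile 0. MKI67 had a difference of -0.87 and CDT1 -0.82, although the probe sets of both differed in sign. NF-kappaB and inflammatory genes had 13 of 17 members higher and a median of 0.49 at percentile 99.95, with CXCL8 at 0.82, CXCL3 at 0.59, TNFAIP3, an NF-kappaB inhibitor, at 0.58 and IL1A at 1.20 or more. The lists of heat shock, endoplasmic reticulum chaperone, integrated stress response, autophagy, p97/VCP, immunoproteasome, assembly, ubiquitin, interferon-stimulated, endoplasmic reticulum degradation and regulator genes all had medians inside the matched random range, between -0.14 and 0.17. The p97/VCP list lay below the range after quantile normalization, at -0.19 and percentile 0.115, and below that of lists not matched on expression, at percentile 2.25, as did the heat shock list at percentile 2.28. VEGFA, the endothelial growth factor gene, had a difference of 1.47.

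Among the largest measured differences in DMSO, IL1RAP, a subunit of the interleukin 1 receptor, was 3.25-fold higher, and HLA-DRB6, MICU3, NACA4P, ABCA8, HELZ2, KLK3, BAIAP2L1, POLK and SH3BP5L were between 2.80-fold and 3.21-fold higher. The probe sets of POLK differed in sign. CBFB, a partner of RUNX transcription factors, was 3-fold lower, DDAH1, an enzyme that degrades a nitric oxide synthase inhibitor, 2.92-fold, SFXN1, a mitochondrial serine carrier whose probe sets differed in sign, 2.77-fold, and IFIT1, an interferon-induced gene, 2.75-fold. SLCO4A1, PHKA1, BATF2, PABIR3 and LAMTOR3 were between 2.46-fold and 2.64-fold lower. LPAR2, ADAM33 and LINGO3 were at least 4.49-fold, 4.38-fold and 4.38-fold higher. ASMTL-AS1, PLEK2 and FBXO43 were at least 4.23-fold, 3.01-fold and 2.96-fold lower. The probe sets of LPAR2 and of ASMTL-AS1 differed in sign.

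In epoxomicin, 27 of the 28 proteasome subunit genes were lower with TCF11 siRNA than with control siRNA, with a median log2 difference of -0.31, and PSMB7 was the exception at 0.03. After quantile normalization all 28 were lower, with a median of -0.40. INHBA was 6.33-fold higher with TCF11 siRNA, the integrin gene ITGB8 5.97-fold, and the prostaglandin synthase gene PTGS2 at least 6.18-fold. Replication genes had a median of -1.25, with 19 of 26 at least 2-fold lower. Of 11559 genes compared, 182 were at least 2-fold higher and 427 at least 2-fold lower. The added poly-A control transcripts had a median log2 difference of 1.85 here.

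The 20S genes had a median of -0.47 at percentile 0 in this comparison, with PSMB6 at -0.61, PSMA7 at -0.60, PSMB3 at -0.58 and PSMB5 at -0.57. The 19S genes had a median of -0.29 at percentile 0.42 of matched lists and 3.30 of lists not matched on expression, which is inside that range, and PSMD8 was lowest at -0.59. Assembly and activator genes had a median of -0.28 at percentile 1.11, and 2.57 without matching, again inside that range, with PSMG4 at -1.35. The NRF2 list had 19 of 25 members lower and a median of -0.32 at percentile 0.14. Its members at least 2-fold lower were EPHX1 at -2.14, AKR1B10 at -1.55, GCLM at -1.47, the biliverdin reductase BLVRB at -1.43, PIR at -1.28 and AKR1C3 at -1.18. Metallothioneins had a median of -0.88 at percentile 0, with MT1H at -1.31.

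Chaperone lists were higher with TCF11 siRNA in epoxomicin. Heat shock genes had 20 of 22 members higher and a median of 0.52 at percentile 100, with DNAJB4 at 1.30, DNAJB1 at 1.12 and HSPH1 at 1.01. All 18 endoplasmic reticulum chaperone genes were higher, with a median of 0.40 at percentile 99.99 and CRELD2 and HYOU1 at 0.86. The integrated stress response list had a median of 0.34 at percentile 99.97, from PSAT1 at -1.42 to the stress gene DDIT4 at 1.57. Cytosolic ribosomal protein genes had a median of 0.37 at percentile 99.99, but 0.01 after quantile normalization, inside the random range. Mitotic genes had a median of -1.01 at percentile 0, with PLK1 at -1.60. The p97/VCP, autophagy, NF-kappaB, interferon-stimulated, immunoproteasome, ubiquitin, regulator and endoplasmic reticulum degradation lists had medians inside the random range, between -0.30 and 0.04.

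PGM2L1 was 4.99-fold higher with TCF11 siRNA in epoxomicin, TMEM132A 4.73-fold, ARVCF 3.77-fold and the collagen gene COL5A1 3.28-fold. NEDD9, C3orf52 and SOX4 were 3.85-fold, 3.42-fold and 3.37-fold higher in their brightest probe sets, but the probe sets of each differed in sign. ERO1B was 3.34-fold higher, IL11 at least 3.85-fold, and SUCNR1 had a log2 difference of 1.81 or more. ELAPOR1 was 5.03-fold lower, the replication factor MCM10 4.45-fold, MCM6 4.35-fold, DTL 4.14-fold, the potassium channel gene KCNN3 4.10-fold, LMNB1, the gene of lamin B1, 3.92-fold, NXPE3 3.85-fold and NOS3, the endothelial nitric oxide synthase, 3.79-fold. The 2 probe sets of MCM6 ranged from -2.12 to -0.10. FGD2, SEL1L3 and RNFT2 were at least 5.55-fold, 5.49-fold and 4.84-fold lower.

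Across 11039 genes the effects of TCF11 siRNA in DMSO and in epoxomicin, which share no array, had a Pearson correlation of 0.22 and a Spearman correlation of 0.21. They shared 11 genes at least 2-fold higher, where independent lists would share 1.51, and 11 at least 2-fold lower, where independent lists would share 1.59. With no floor the Pearson correlation was 0.03.

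The last comparison asked whether the response to epoxomicin differed with TCF11 siRNA, as the epoxomicin effect with TCF11 siRNA minus that with control siRNA. The 28 proteasome subunit genes together had a median difference of -0.01, with 14 above 0 and 14 below, inside the random range of -0.05 to 0.26. Taken singly, the 20S genes had a median of -0.22, below their random range, and the 19S genes 0.06, inside theirs. Heat shock genes responded more with TCF11 siRNA, with 20 of 22 members above 0 and a median of 0.63. NRF2 antioxidant genes had 19 of 25 members below 0 and a median of -0.45. Replication genes had a median of -1.06 and mitotic genes -0.65. The difference was at least 1 in size in 220 genes above 0 and 596 below, of 12263 compared. These differences draw on the TCF11 siRNA arrays, which had the lowest and the highest signal of the added poly-A control transcripts. That signal was 393 in DMSO and 3148 in epoxomicin with TCF11 siRNA, against 1563 and 890 with control siRNA. For these transcripts the difference of the effects was 3.82 in log2, or 14.1-fold.

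The proteasome lists were also taken singly, without a test of 1 against the other. The 20S genes had a median of -0.22 at percentile 0.15 of matched lists, with PSMB5 at -0.51, PSMB6 at -0.46 and PSMA7, whose probe sets differed in sign, at 0.45. That median was at percentile 16.6 of lists not matched on expression, inside their range. After quantile normalization it was -0.38 at percentile 0.105, below the matched range, with 12 of 13 genes below 0. The 19S genes had a median of 0.06 at percentile 36.7. For all 28 together the median was 0.04 after centring on the median, on the other side of 0. After quantile normalization it was -0.20, with 19 of 28 below 0, at percentile 2.70 and just inside the random range. The immunoproteasome, assembly, ubiquitin, p97/VCP, autophagy, metallothionein, NF-kappaB and regulator lists had medians inside the matched random range, between -0.43 and 0.14. The NF-kappaB list, at -0.43, lay below the range of lists not matched on expression, at percentile 0.88.

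Stress genes with larger responses under TCF11 siRNA included DNAJB1 at 1.40, HSPB1 at 1.37, HSPH1 at 1.11, HERPUD1 at 1.08 and ATF3 at 1.34. The heat shock list lay at percentile 100, the endoplasmic reticulum chaperone list had a median of 0.42 at percentile 99.98, and the integrated stress response list 0.41 at percentile 100. The list of degradation from the endoplasmic reticulum had a median of 0.21 at percentile 97.6, just above the matched range, and lay inside the range after centring on the median, after quantile normalization and without matching. Among antioxidant genes EPHX1 had a difference of -1.99, its epoxomicin effect being 0.44 with control siRNA and -1.55 with TCF11 siRNA. Genes with smaller responses in the same direction included AKR1B10 at -1.82, AKR1C3 at -1.45, BLVRB at -1.20, PIR at -1.11 and the glutathione reductase gene GSR at -1.10. That list lay at percentile 0. Its member SLC7A11 had a difference of 0.53 and HMOX1 -0.83.

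Interferon-stimulated genes had 16 of 19 members below 0 and a median of -0.40 at percentile 1.91, with OAS1, an RNA sensor, at -2.17 and IFIT1 at 1.58. Ribosomal protein genes had all 25 members above 0 and a median of 0.43 at percentile 99.98, a direction that flipped to -0.05 after quantile normalization, with 10 members above 0 and 14 below. Replication genes were led by MCM6 at -1.53, CDC6 at -1.52 and MCM10 at -1.51, and CDT1 was the opposite extreme at 0.85. The probe sets of MCM6 differed in sign. Both division lists lay at percentile 0.

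INHBA had the largest positive difference of the effects, 2.68, followed by HDAC5, a histone deacetylase, at 2.41, LIFR at 2.29, JPT2 at 1.78, HBEGF at 1.75, TUT1 at 1.73, ZYG11A at 1.70, CNTROB at 1.69, FAM13A-AS1 at 1.68 and RAB15 at 1.67. The probe sets of LIFR, JPT2 and CNTROB differed in sign, and without the _s_at and _x_at probe sets CNTROB had -1.42. NXPE3 had the most negative measured difference, -2.62, with probe sets of both signs, followed by TMEM17 at -2.22, OAS1, DYNC2LI1 at -2.13, HS3ST1 at -2.06, BCKDHB at -2.06, SPP1, the gene of osteopontin, at -2.05, EPHX1, ZBED5-AS1 at -1.99 and ELAPOR1 at -1.97. The bounds furthest from 0 were at least 4.61-fold for ASMTL-AS1, 4.60-fold for TTC38 and 3.67-fold for HDAC11 on the positive side. On the negative side they were at least 12.1-fold for FGD2, 12.1-fold for MINDY3 and 7.48-fold for LPAR2, and the probe sets of FGD2 and of LPAR2 differed in sign.

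**Figure D3:**
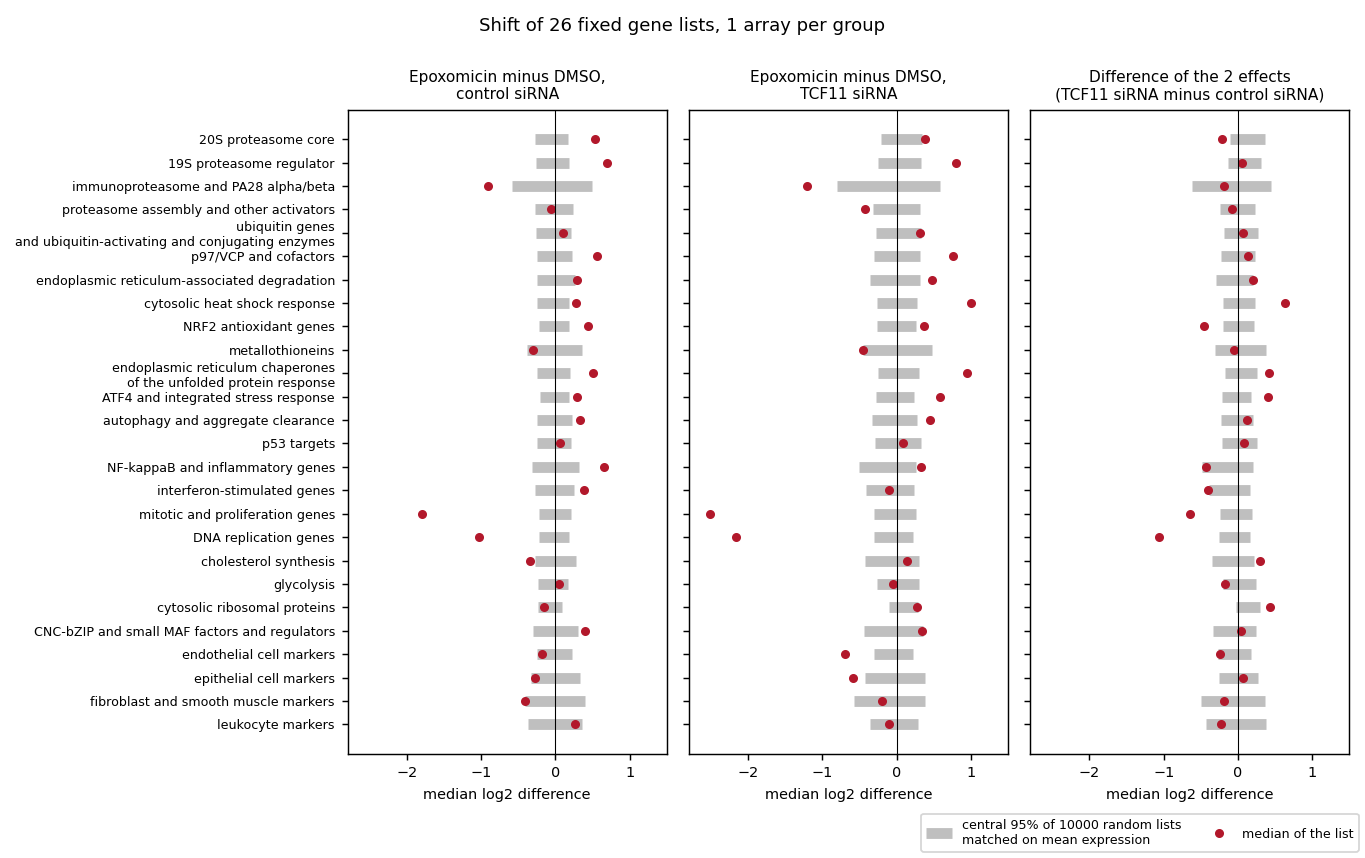
Median log2 difference of the 26 gene lists (points) for epoxomicin against DMSO with each siRNA and for the difference of the 2 effects, with the central 95% of 10000 random lists matched on mean expression (grey bars). In the panel of differences, 6 lists lie above and 5 below the bars, among them the heat shock list at 0.63, the NRF2 list at -0.45 and the replication list at -1.06, and the ribosomal protein list at 0.43 flips to -0.05 after quantile normalization.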

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

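The tests of the spike-in pattern and of the NFE2L1 signal left after silencing, the test of a general signal loss and that of a uniform scaling of the response were chosen after the result was seen. The tests by quantile normalization and by brightness were set beforehand.

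The poly-A control transcripts of bacterial origin, which are added to the RNA before labelling and enter no comparison, differed between arrays. Their geometric mean signal was 1563 and 890 with control siRNA in DMSO and epoxomicin, and 393 and 3148 with TCF11 siRNA, so that the TCF11 siRNA, epoxomicin array was 2.01-fold above the control siRNA, DMSO array. With TCF11 siRNA the epoxomicin array exceeded the DMSO array by a median of 2.998 in log2, between 2.88 and 3.13 for the 4 transcripts, which is what a different ratio of spike-in to sample RNA would give. Gene probe sets of similar signal had a median shift of 0.00 (-0.0021) there, with 95% of them between -1.62 and 1.26. The common trimmed mean already held the bulk of such probe sets near 0, so this value by itself could not test scaling that depends on signal. It shows only that the spike-ins shifted apart from gene probe sets of similar signal. A smaller effect of such scaling is not excluded. Ribosomal protein genes, for example, had a median TCF11 siRNA effect in epoxomicin of 0.37, and of 0.01 after quantile normalization. The spike-ins shifted by -0.81 with control siRNA, but between the DMSO arrays they already differed by -2.00 (TCF11 siRNA minus control siRNA). Without a known amount added per sample, this cannot tell whether epoxomicin lowers the mRNA share. Whether the volume added or the mRNA content of the sample differed stays open, and leaving out that array is not possible with 1 array per group.

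Proteasome subunit genes were higher with epoxomicin also under TCF11 siRNA. Scaling that depends on signal is argued against, since their median was still 0.58 after quantile normalization, outside the random range of -0.21 to 0.12. Compression of bright signals could hide a lost response, which would leave the dimmer genes lower than the brighter genes in the difference of the effects. Its median was instead 0.05 in the dimmer genes and -0.14 in the brighter genes. That gap of 0.19 lay within the -0.30 to 0.30 that random splits gave. The brighter genes were mostly core genes and the dimmer genes mostly regulator genes, so the split cannot separate brightness from subunit class. Compression therefore stays open. NFE2L1 product left after silencing may carry the response, because 25.98% of its signal was left in epoxomicin, 1322 against a floor of 104. That probe set is marked for possible cross-hybridization, so the signal left need not all come from NFE2L1. A response carried by what is left cannot be told apart from a response by another route without a stronger silencing.

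Replication and mitotic genes were lower still with epoxomicin under TCF11 siRNA, and stress lists higher. For the 50 division genes the difference of the effects was -0.81 after quantile normalization, which argues against scaling. Their median TCF11 siRNA effect in epoxomicin was -1.12 where expression-matched lists gave -0.17 to 0.12. This argues against a general loss of signal at their level. It pools the mitotic and replication lists, each already at percentile 0 in that comparison, so it is not separate support. A uniform strengthening of the epoxomicin response did not account for all list shifts on these arrays, judged from the 2 epoxomicin effects, which share no array. The common factor for control siRNA effects that left the fewest lists unexplained was 1.3. With it, the effects with TCF11 siRNA still lay outside the random range in 10 of 26 lists, where lists of unrelated genes would give 1.3. Among them were heat shock and endoplasmic reticulum chaperones above and NRF2, 20S core and replication genes below. The mitotic list was not among them. The ribosomal protein list was, although its difference of the effects went from 0.43 to -0.05 after quantile normalization. Members of a list can vary together, unlike random genes, so the count does not show how far 2 cultures would differ anyway. A difference between the cultures, which random lists do not cover, is not excluded.

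In 6 genes of 11147 the epoxomicin differences were at least 2-fold in opposite directions with the 2 siRNAs, which was not tested, and none of the 6 was above the floor on all 4 arrays. The values of the difference of the effects are therefore bounds, at least this far from 0, of -3.60 for FGD2, -3.59 for MINDY3, -2.32 for MMEL1, -2.46 for S100A4, -2.44 for SPDEF and 2.20 for TTC38.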

How the results depend on the processing

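All alternatives were set before the data were examined, except that the position of each list among random lists under the 2 other scalings was added after the results were seen. The numbers here count each result once per alternative, so they are not numbers of lists or genes. Of list medians, 871 moved by less than 1 SD of random lists, 161 by more, and 3 outside the random range changed sign. Of values of named genes, 1322 moved by less than the technical gauge, 160 by more, and 2 of at least 2-fold changed sign. The alternatives differed in this. Without _s_at and _x_at probe sets, 76 list medians moved by less and 48 by more. For values of named genes the numbers were 129 and 32 there, whereas with median centring all 229 moved by less. Counts stayed within 1.5 times the main ones under the 2 scalings and the 2 probe set choices (40 values) and not under the floors and thresholds (50 values), which alter by construction which genes can pass. Of 65 list results outside the random range, 1 came inside with median centring, 6 with quantile normalization and 7 without matching on expression, and of 65 inside, 1, 7 and 6 came outside. With no floor the correlations across genes were 0.149 for the epoxomicin effects and 0.0288 for the TCF11 siRNA effects. Leaving out a replicate, or the TCF11 siRNA, epoxomicin array, cannot be done with 1 array per group. No paired fit across the siRNAs was run, since the difference of the epoxomicin effects, itself a result here, would be its only residual.

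With no floor, genes at least 2-fold higher and lower were 2388 and 2490 for epoxomicin with control siRNA, 2297 and 3447 with TCF11 siRNA, 2296 and 1840 for TCF11 siRNA in DMSO, 2111 and 2551 in epoxomicin, and 2632 and 3581 for the difference of the effects. In the same order, the floor at the 25th percentile gave 1280 and 1318, 1293 and 2214, 1163 and 816, 1028 and 1369, and 1442 and 2215. The floor at the 75th percentile gave 189 and 230, 289 and 433, 13 and 16, 72 and 135, and 68 and 126. A log2 difference of at least 1.5 gave 106 and 128, 113 and 356, 12 and 6, 26 and 81, and 42 and 150. A threshold of 1.5-fold gave 1358 and 1407, 1539 and 2371, 734 and 391, 954 and 1415, and 970 and 1905.

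For the 20S core, the median in DMSO was -0.22 with median centring and the mean -0.24, and the difference of the effects was -0.38 with quantile normalization. The 19S median in DMSO was -0.18 with quantile normalization. Signs changed for ribosomal proteins in the difference of the effects (-0.047 with quantile normalization), epithelial markers with epoxomicin and TCF11 siRNA (0.0499 with the floor at the 25th percentile) and in DMSO (0.29 without _s_at and _x_at probe sets), SQSTM1 with control siRNA (-0.37 without those probe sets) and CNTROB in the difference of the effects (-1.42 without them). The cause was not tested.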

Other observations

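The lists were fixed before the data were examined, and their positions after other scalings were computed after the result was seen. Endothelial marker genes had a median log2 difference of -0.70 with epoxomicin under TCF11 siRNA, at percentile 0, with 18 of 22 measured members lower, and of -0.18 with control siRNA, inside the random range. MMRN2, an endothelial matrix protein, had differences of -2.20 and -2.00 in that order and PECAM1, an adhesion molecule of endothelial junctions, -1.59 and -2.03, although probe sets of PECAM1 differed in sign with control siRNA. THBD, the gene of thrombomodulin, was at least 2-fold higher with both siRNAs. In the other 3 comparisons this list lay inside the matched range, with medians of -0.01 and -0.11 for TCF11 siRNA in DMSO and epoxomicin and -0.24 for the difference of the effects, which lay below the range at -0.28 and percentile 2.13 after quantile normalization. Epithelial markers had medians of -0.28 with control siRNA and -0.58 with TCF11 siRNA for epoxomicin, the latter at percentile 0.56 over 7 genes, with KRT7 at -1.54, although the floor at the 25th percentile gave 0.0499 and lists not matched on expression put it inside the range. For TCF11 siRNA in DMSO they had -0.33 at percentile 0.855 over 5 genes, but -0.13 after quantile normalization, inside the range, and 0.29 without _s_at and _x_at probe sets. Fibroblast markers had a median of -0.41 at percentile 2.48 with control siRNA, over 6 genes, inside the range after quantile normalization and without matching, and were inside it in the other 4 comparisons. For TCF11 siRNA in DMSO their median of 0.30 was inside, but above the range at 0.34 after centring on the median and 0.36 after quantile normalization. Leukocyte markers, of which 3 to 6 were measured, were inside the range in all 5.

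Cholesterol synthesis genes had a median of -0.34 at percentile 0.74 with epoxomicin and control siRNA and 0.13, inside the range, with TCF11 siRNA. The difference of the effects was 0.29 at percentile 99.5, with 14 of 17 members above 0, led by SQLE, the squalene epoxidase, at 0.79, INSIG1 at 0.74 and LSS at 0.74. In DMSO the list had a median of -0.18 at percentile 0.895 with TCF11 siRNA, with DHCR7 at -0.74. Glycolysis genes had a median of -0.33 at percentile 0.06 with TCF11 siRNA in epoxomicin, with SLC2A1 at -0.77 and ENO1 at -0.57, and -0.18 at percentile 0.63 in DMSO, the latter inside the range after quantile normalization (-0.10). With epoxomicin this list was inside the range with either siRNA, and the difference of the effects, -0.17 and inside, lay below the range at -0.31 after quantile normalization. Targets of p53 had a median of 0.13 with TCF11 siRNA both in DMSO, at percentile 98.7, and in epoxomicin, at percentile 87.5, where the random range was wider. In DMSO they were led by MDM2 at 0.58, whose probe sets differed in sign, and without matching the list was at percentile 85.3, inside the range. Metallothioneins had medians of -0.31 and -0.45 with epoxomicin under control and TCF11 siRNA, both inside the range, and ribosomal proteins -0.16 and 0.28, also inside, the latter flipping to -0.03 after quantile normalization and lying above lists not matched on expression, at percentile 99.1.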
